A study of Mus musculus with 6 samples.

How the data were processed

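RNA of the vomeronasal organ was measured on 6 Affymetrix whole-transcript arrays, 3 of wild-type and 3 of AP-2e null mice at postnatal day 17. Per the labels' protocols, the organs were taken straight after death, total RNA was extracted with a column kit, and biotin-labelled target was made from it by the Affymetrix whole-transcript protocol. The deposited table holds log2 signals, 1 value per probe set and array, and per the submitters' processing notes the tools were RMA, which corrects background, equalises the arrays by quantiles and summarises probes, and the Transcriptome Analysis Console. Their versions and settings are not given in the sources used here. No scanner files were used here, so background and probe-level effects were taken as the authors left them. Genotypes and replicate numbers came from the sample titles, which call the samples biological replicates. How many animals went into a sample is not given in the sources used here, so p-values of single genes refer to spread between samples, 3 per genotype.

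The table held 41345 probe sets. The platform annotation named 1 gene for 23521 of them, several genes for 1814 and none for 16010. Symbols were checked by Entrez identifier in a RefSeq gene table (assembly GRCm38.p6), which matched 23328 of the 1-gene probe sets and changed 0 symbols, and the other 193 kept the platform's symbol. No genome build is given in the sources used here, so the gene table served only for names and for which genes are neighbours. For each gene the probe set with the highest mean over all 6 arrays was kept, which left 22180 genes, of which 1082 had more than 1 probe set. No filter on dim genes was set. On all 6 arrays the same value stood for 134 probe sets and for 77 of the tested genes, and 22468 probe sets had 6 different values.

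Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes. This fit shares information on the spread across genes, so its p-values do not rest on a gene's own 3 samples per genotype alone. Differences are AP-2e null minus wild-type on the log2 scale with the fit's standard error (SE), and group values are means ± SD over 3 arrays. Of the 36 gene lists, 35 had the minimum of 3 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera compares the genes of a list with all other genes, so these p-values do not measure the spread between samples alone. Each list was tested again with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance in the same direction. For 41 genes of the lists no 1-gene probe set was found. Differences between the means of paired lists were tested with exact 2-sided permutation over the 20 label arrangements, where the smallest p that 3 against 3 allows is 0.1.

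The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Tfap2e first, then the 15 largest rises and the 15 largest falls among genes that passed and whose groups did not overlap, filled by unadjusted p where fewer passed. It further took up to 4 members of each list with the smallest p, and every member of the basal, apical and general sensory neuron lists, and it named no predicted genes, clone names or small RNA genes. The other settings tried were other variance moderation, the mean of a gene's probe sets, every probe set by itself, a filter on the dimmest 30% of genes, median centring, repeated quantile normalization, cyclic loess, array weights, a plain one-way test per gene, a rule of at least 2-fold with unadjusted p, the replicate number as a block, and leaving out each array in turn. A covariate for the array with high Xist signal, a comparison of 2 against 2 arrays, a fit without the constant genes and list tests without V2R genes in the background were chosen after seeing the data.

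The scripts were tested on simulated data for this comparison with 22180 genes. At a true log2 change of 1, 88 of 100 changed genes were recovered, and at a log2 change of 2, 99 of 100. Of 200 random unshifted lists, 10 reached an unadjusted p under 0.05 with camera. The simulated genes varied independently, each with the spread that limma gives after sharing information across genes. These rates therefore do not cover genes with a larger spread. Nor do they cover lists whose genes vary together, as the V1R genes did here (estimated correlation 0.37). Receptor families consist of near-identical genes whose probes can bind related transcripts, so values of single V1R, V2R, odorant receptor and H2-M genes are uncertain. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.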

Results

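The vomeronasal organ (VNO) is the chemosensory organ in the nasal septum with which mice detect pheromones and other social cues. Its sensory neurons belong to an apical class, which uses V1R receptors and the G protein subunit Gnai2, and a basal class, which uses V2R receptors and the subunit Gnao1. AP-2e, the protein of the gene Tfap2e, is a transcription factor of the AP-2 family. RNA of VNOs from 3 wild-type and 3 AP-2e null samples at postnatal day 17 was measured on 1 array each, to find which genes differed between the genotypes. Values are log2 signals. The median over the 41345 probe sets lay between 4.997 and 5.079 on every array, and 22180 genes were tested. Across genes, which are not independent replicates, pairs of arrays correlated with r between 0.971 and 0.985. Wild-type replicate 3 had the lowest mean r with the other arrays, 0.973. The number of arrays limits the precision.

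Tfap2e itself had lower signal on every AP-2e null array than on every wild-type array. In wild-type replicates 1, 2 and 3 its log2 signal was 6.46, 6.76 and 6.92, and in AP-2e null replicates 1, 2 and 3 it was 5.97, 6.09 and 6.03. The means were 6.71 ± 0.23 and 6.03 ± 0.06 (SD, n = 3 each), a difference of -0.68 (SE 0.13) or 1.60-fold lower, with an adjusted p of 0.431 over all genes. This gene therefore did not pass the threshold over all genes, and it passed when adjusted over the 5 AP-2 genes alone (adjusted p = 0.00991). Where its probes lie relative to the altered part of the gene is not given in the sources used here, so the size of the difference says little about the allele. The other AP-2 genes measured passed neither way, with Tfap2a at 0.06, Tfap2c at 0.15 and Tfap2d at 0.02 on the log2 scale.

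The genes that fell in AP-2e null VNOs were mostly V2R receptor genes. Vmn2r69 fell from 8.30 ± 0.15 to 2.53 ± 0.20 (SD, n = 3 each), which is 54.6-fold (SE 0.13 on the log2 scale, adjusted p = 0.000277 in limma). Vmn2r9 fell 53.6-fold, Vmn2r17 fell 40.7-fold, Vmn2r81 fell 34.2-fold and Vmn2r67 fell 29.5-fold. Vmn2r33, the V2R gene with the highest wild-type mean in this group at 11.49 ± 0.07, fell to 6.89 ± 0.31. The remaining genes among the 15 largest falls were Vmn2r98, Vmn2r74, Vmn2r49, Vmn2r105, Vmn2r37, Vmn2r120, Vmn2r104, Vmn2r66 and Vmn2r83, and the smallest fall of these was 18.2-fold, for Vmn2r83. Of these 15 genes, 9 passed whichever single array was left out, and Vmn2r98, Vmn2r74, Vmn2r49, Vmn2r105, Vmn2r37 and Vmn2r66 did not. In all, 48 genes fell and 2 rose, and the 48 were 42 V2R genes, the V2R pseudogene Vmn2r-ps60 and 5 others. At an unadjusted p under 0.05 there were 553 lower and 422 higher genes. The values of the genotypes did not overlap for 7.06% of genes, where chance alone gives 10% for 3 against 3, and they did not overlap for any of the 50 genes that passed. With a single array left out, the number of genes that fell went to between 17 (without wild-type replicate 2) and 32 (without wild-type replicate 3), and it was 20, 26, 20 and 23 without wild-type replicate 1 and AP-2e null replicates 1, 2 and 3. Near-identical V2R genes can share probes, so the values of single members are uncertain.

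**Figure D1:**
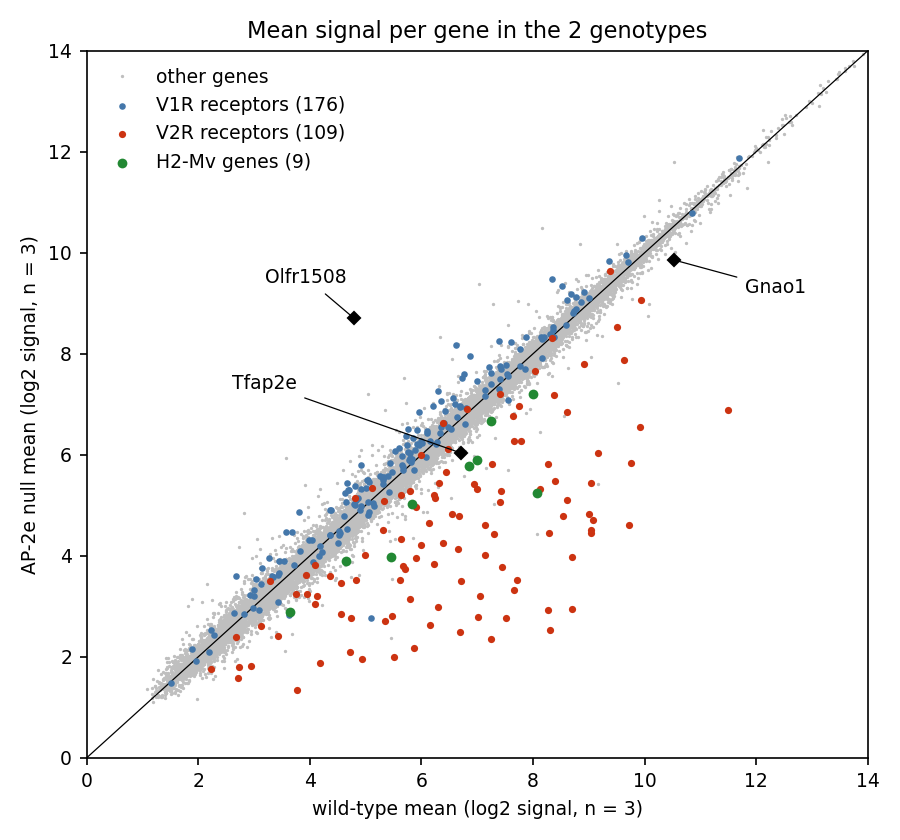
Mean log2 signal of each gene in wild-type (x axis) and AP-2e null (y axis) VNOs, n = 3 arrays each, with 1 point per gene and the line of equal signal. V2R genes lie mostly below the line (102 of 109 were lower), V1R genes have a median difference of 0.22 and lie between -2.32 and 1.54 (142 of 176 were higher), and the black diamonds mark Tfap2e, Gnao1 and Olfr1508.

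V2R genes fell as a family. Of 109 measured V2R genes, 102 were lower in AP-2e null VNOs, 42 fell past the threshold over all genes, and 89 fell and 1 rose when adjusted over the list alone. In the plain one-way test only 3 V2R genes passed, and 84 had an unadjusted p under 0.05, against 91 in limma. The mean difference of the 109 genes was -2.09 and the median -1.78, and the mean signal of the list went from 6.57 ± 0.20 to 4.48 ± 0.09 (SD, n = 3 each, camera adjusted p = 6.83e-105). The call held with an estimated correlation (adjusted p = 0.0199 with an estimated correlation). The 7 members of V2R family C, the co-receptors that basal neurons make beside another V2R, were all lower, with a mean difference of -1.76. Of these, 4 fell past the threshold and 7 fell when adjusted over the list alone: Vmn2r5 fell 7.84-fold, Vmn2r4 fell 6.98-fold, Vmn2r6 fell 3.39-fold and Vmn2r7 fell 3.37-fold. The family C list had a camera adjusted p of 1.96e-21, and an adjusted p = 0.0596 with an estimated correlation. In the plain one-way test 0 of its genes passed, and 7 had an unadjusted p under 0.05. For 17 of the 42 V2R genes that fell, the AP-2e null mean lay under the lower quartile of the arrays' probe sets, 3.62, so their fold changes may be understated.

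Of the V2R genes, 7 had higher means in AP-2e null VNOs, and none of these passed over all genes. They were Vmn2r112 at 0.34, Vmn2r113 at 0.26, Vmn2r22 at 0.24, Vmn2r68 at 0.23, Vmn2r19 at 0.22, Vmn2r26 at 0.08 and Vmn2r116 at 0.00, named here after their values were seen. Vmn2r113 was the member that rose when adjusted over the list alone, but the mean of its probe sets gave -0.25, and Vmn2r116 changed sign without some single arrays. For Vmn2r68 and Vmn2r26 the SE, 0.58 and 0.30, was larger than the difference. The 7 neighbouring genes Vmn2r111 to Vmn2r117 had a mean difference of -0.17, against -2.22 for the other 102 V2R genes.

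**Figure D2:**
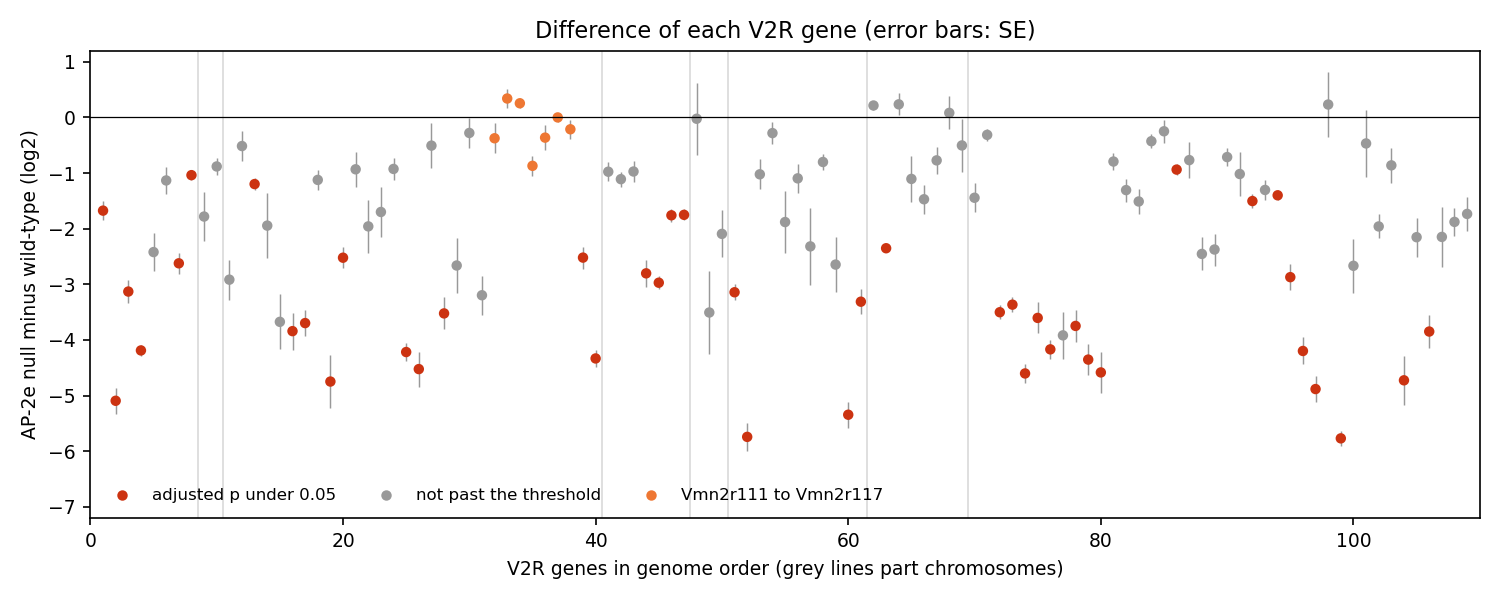
Log2 difference (AP-2e null minus wild-type, n = 3 arrays each) of each of 109 V2R genes in the order of a reference gene table, with bars for the SE of the limma fit and grey lines between chromosomes. Red points are the 42 genes that fell past the threshold, and the orange points of Vmn2r111 to Vmn2r117 lie between -0.87 and 0.34, where Vmn2r113 changed sign when its probe sets were averaged and Vmn2r116 changed sign without some single arrays.

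H2-Mv genes, MHC class Ib genes that a part of the basal neurons make together with V2Rs, fell as well. All 9 measured members were lower, with a mean difference of -1.13 (camera adjusted p = 3.93e-14, and adjusted p = 0.0251 with an estimated correlation). H2-M1 fell 7.07-fold, from 8.07 ± 0.49 to 5.25 ± 0.17 (SD, n = 3 each, adjusted p = 0.0271 in limma), and was the only member to pass over all genes, while 9 fell when adjusted over the list alone. H2-M10.1 at -0.81, H2-M10.6 at -0.80 and H2-M10.2 at -0.76 were among the members that did not pass over all genes. In the plain one-way test 0 of the 9 members passed, and 8 had an unadjusted p under 0.05. H2-M1 passed in 8 of 18 alternatives and no longer when any single array was left out, and its difference then lay between -3.05 and -2.57 with adjusted p between 0.0625 and 0.259.

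Beside H2-M1, 4 genes outside the receptor families fell, named here after their values were seen. Cfap300, a gene of cilium assembly, fell by 1.09 on the log2 scale from 10.08 to 8.99 (adjusted p = 0.00996 in limma). Sphkap, which codes for an anchor protein of protein kinase A, fell by 1.42 (adjusted p = 0.0155). Tafa1, which codes for a secreted protein of neurons, fell by 1.17 (adjusted p = 0.0330), and Cnpy1 fell by 0.91 (adjusted p = 0.0386). With single arrays left out, Cfap300 passed only without AP-2e null replicate 1, Sphkap only without wild-type replicate 3, and Tafa1 and Cnpy1 not at all. Over all alternatives their differences lay between -1.15 and -1.04, -1.53 and -1.33, -1.23 and -1.07, and -0.99 and -0.86, and they passed in 10, 9, 8 and 8 of 18 alternatives. With every probe set by itself, 39 probe sets of 1 gene fell. Of these, 37 were of V2R genes, so not all of these 4 genes kept their calls there.

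Both genes that rose are odorant receptor genes. Olfr1508 rose 15.1-fold, from 4.79 ± 0.81 to 8.71 ± 0.10 (SD, n = 3 each, SE 0.40 on the log2 scale, adjusted p = 0.0423 in limma). Olfr743 rose 1.51-fold, from 3.89 ± 0.05 to 4.49 ± 0.07 (adjusted p = 0.0493). The odorant receptor list had no call as a whole: its 1088 genes had a mean difference of 0.02 (camera adjusted p = 0.421, and adjusted p = 0.630 with an estimated correlation), with 2 past the threshold over all genes and 0 when adjusted over the list alone, where 78 had an unadjusted p under 0.05 in limma and 35 in the plain one-way test, which called 0. Olfr1508 passed in 8 of 18 alternatives, with differences between 3.58 and 4.36 and adjusted p between 0.0176 and 0.552. It kept its call without wild-type replicate 1 and lost it when any other array was left out. With all arrays it lost it with array weights (adjusted p = 0.0569), the plain one-way test (0.430) and the replicate block (0.196). The sex covariate (0.366) marks AP-2e null replicate 1 alone, so it repeats the fit without that array. Olfr743 passed in 3 of 17 alternatives. It lost its call when any array was left out, with differences between 0.57 and 0.64. With all arrays it lost it when its probe sets were averaged (0.31 on the log2 scale), with trend and robust moderation (adjusted p = 0.0890) and with median centring (0.0633). Array weights (0.0571), the plain one-way test (0.214) and the replicate block (0.400) also lost it. The sex covariate (0.312) again repeats the fit without AP-2e null replicate 1. With every probe set by itself, 0 probe sets of 1 gene were higher past the threshold, so both odorant receptor genes lost their calls there.

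The next genes by p among the higher ones did not pass, though 3 of them did in some alternatives. They were led by the V1R gene Vmn1r73 at 1.54 (adjusted p = 0.0589) and Rabggtb, a subunit of the enzyme that attaches lipid anchors to Rab proteins, at 0.87 (adjusted p = 0.0593), which passed in 6 and 4 of 18 alternatives. Odorant receptor genes followed, with Olfr1350 at 1.08, Olfr1349 at 0.93 (past the threshold in 1 of 17 alternatives), Olfr549 at 0.70, Olfr681 at 0.64, Olfr1094 at 0.44 and Olfr1097 at 0.36. The others were Klra5 at 0.49, Pramel47 at 0.47, Pm20d1 at 0.47, Rtp1, a receptor-transporting protein, at 0.44 and Apbb1ip at 0.38. Means of Olfr1094, Olfr1097, Pramel47 and Klra5 lay under the lower quartile of the arrays' probe sets, 3.62, in both genotypes. That of Olfr1349 lay under it in wild-type VNOs, at 3.45. The differences of these genes may therefore lie in background signal.

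V1R receptor genes were slightly higher as a list, and no single member passed over all genes, though Vmn1r73 did in 6 of 18 alternatives (adjusted p between 0.0325 and 0.557). Of 176 measured genes, 142 had higher means in AP-2e null VNOs, 0 passed over all genes, 1 rose when adjusted over the list alone, and 27 had an unadjusted p under 0.05 in limma (13 in the plain one-way test, which also called 0). Vmn1r73 was followed by Vmn1r84 at 1.14, Vmn1r68 at 0.82 and Vmn1r5 at 0.58. Of the 34 lower members, Vmn1r188 had the largest difference of the list, from 5.09 ± 2.84 to 2.76 ± 0.59 (SD, n = 3 each), which is -2.32 with an unadjusted p of 0.154, and it is named here after its value was seen. The mean difference of the list was 0.24 and the median 0.22 (camera adjusted p = 3.64e-11), and the call was lost at adjusted p = 0.534 with an estimated correlation. The list means were 5.78 ± 0.30 and 6.03 ± 0.12 (SD, n = 3 each) and overlapped between genotypes. Without wild-type replicate 2, whose list mean of 5.43 was the lowest, the mean difference was 0.07.

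Per array, the V2R mean minus the V1R mean was 0.79 ± 0.21 in wild-type and -1.55 ± 0.05 in AP-2e null VNOs (SD, n = 3 each). The difference of -2.34 had an exact permutation p of 0.1, the smallest that 3 against 3 allows.

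Markers of the basal neurons other than receptors were lower as a list, and none passed alone. Calr4, a calreticulin-like chaperone, differed by -1.10 (adjusted p = 0.141), Gnao1 by -0.68 (adjusted p = 0.331), the adhesion gene Kirrel3 by -0.50 and the axon guidance receptor Robo2 by -0.49, while Gng8, a G protein gamma subunit, differed by 0.06. Of the 5 genes, 0 passed over all genes in limma or in the plain one-way test, 4 had an unadjusted p under 0.05 in limma (3 in the plain test), and 4 fell when adjusted over the list alone. The mean difference was -0.54 (camera adjusted p = 1.29e-05, and adjusted p = 0.137 with an estimated correlation), and fry gave an adjusted p of 0.00641. Calr4 passed only without wild-type replicate 3, at -0.93 and adjusted p = 0.0384, where its adjusted p over all alternatives reached 0.747.

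Apical markers showed no call. The 7 genes had a mean difference of 0.05 (camera adjusted p = 0.239), with Gng2 at 0.36, Meis2, a transcription factor of apical neurons, at 0.26, Gnai2 at 0.11, Ncam2 at 0.08, Pde4a at -0.03, Nrp2 at -0.06 and Kirrel2 at -0.35, and 3 of them had an unadjusted p under 0.05 in limma. The mean of the basal markers minus that of the apical markers was 0.42 ± 0.05 in wild-type and -0.18 ± 0.01 in AP-2e null VNOs (SD, n = 3 each). This difference of -0.60 had an exact permutation p of 0.1, and with medians over the lists it was -0.09 (exact permutation p = 0.7).

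Genes shared by both neuron classes showed no call as a list, with a mean difference of -0.06 (camera adjusted p = 0.377). Trpc2, the transduction channel of VNO neurons, differed by -0.04, Omp, the marker of mature sensory neurons, by -0.41, the chloride channels Ano1 and Ano2 by 0.06 and -0.40, Gnb1 by -0.10, Reep1 by 0.05 and Cnga4 by -0.11. With Rtp1, 8 genes were measured, and 1 rose and 1 fell when adjusted over the list alone (Rtp1 and Ano2).

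**Figure D3:**
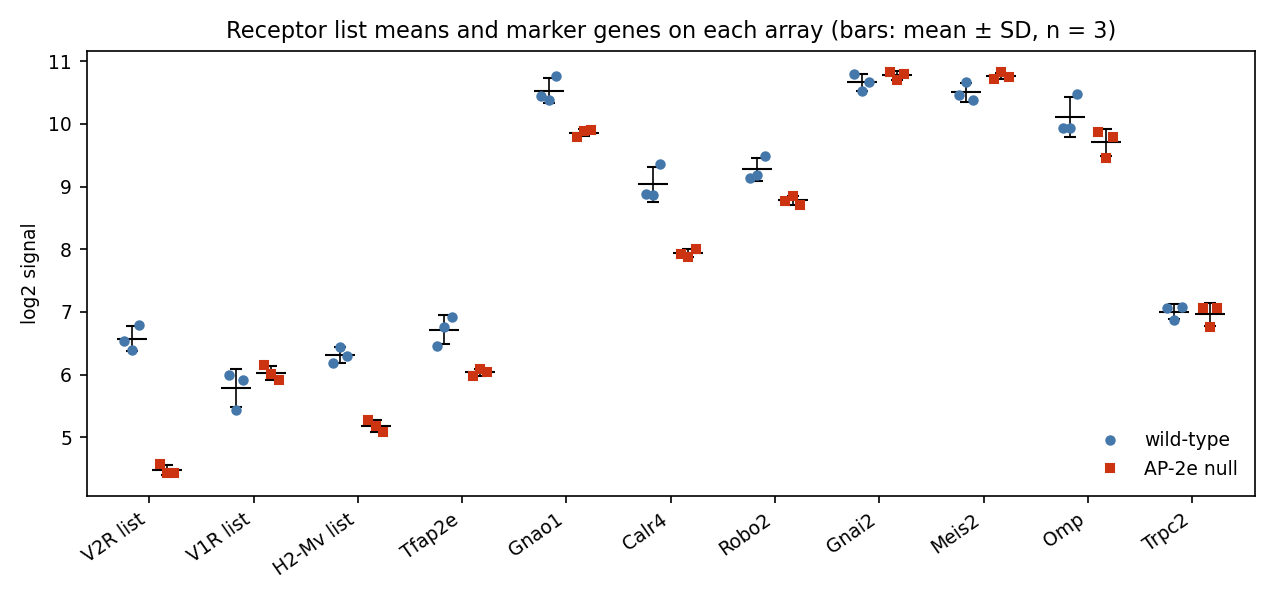
Log2 signal on each of the 6 arrays for the means of the V2R, V1R and H2-Mv lists and for 8 single genes, with bars for the mean ± SD (n = 3). V2R list means lie at 4.42 to 4.58 in AP-2e null and 6.39 to 6.78 in wild-type VNOs, whereas V1R list means overlap.

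Markers of other cell types in or beside the organ were measured on the same arrays. At the preset correlation, lists of neutrophils (mean difference 0.44), smooth muscle and pericytes (0.15), endothelium (0.09) and cartilage (0.49) were higher, and lists of multiciliated respiratory cells (-0.31) and skeletal muscle (-0.33) were lower, with camera adjusted p between 0.00335 and 0.0356. None of these calls held, with adjusted p between 0.534 and 0.615 with an estimated correlation, and 0 genes of these lists passed in limma or the plain test. At an unadjusted p under 0.05 in limma there were 1 of the neutrophil genes, 2 of the smooth muscle and pericyte genes and 0 of the others, and 1 of them, Pdgfrb, rose when adjusted over its list alone. Examples are Mpo, a neutrophil granule enzyme, at 0.62, Pdgfrb, a pericyte receptor, at 0.26, Foxj1, the regulator of motile cilia, at -0.40 and the muscle myosin Myh4 at -1.17. The cartilage list stood at 7.97 on AP-2e null replicate 2 and between 6.08 and 6.34 on the other arrays, and without that array its mean difference was -0.13. The cartilage call was also lost when any wild-type array was left out (0.43 to 0.55). The neutrophil call was lost without wild-type replicate 3 (0.21), and that of smooth muscle and pericytes without wild-type replicate 1 (0.07) or AP-2e null replicate 1 (0.11). Endothelium lost it without wild-type replicate 1 or 2 or AP-2e null replicate 1 or 2 (0.04 to 0.09), skeletal muscle without wild-type replicate 2 or AP-2e null replicate 1 or 3 (-0.28 to -0.15), and multiciliated cells without wild-type replicate 1 or 2 or AP-2e null replicate 1 (-0.24 to -0.17).

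Genes of activity and of protein folding stress had calls of the same kind. The activity-regulated list was higher by 0.32 on average (camera adjusted p = 0.0287, and adjusted p = 0.534 with an estimated correlation), with Egr1, an immediate early transcription factor, at 0.67, the only member to rise when adjusted over the list alone. Nr4a1 at 0.70, Ier2 at 0.28 and Egr2 at 0.25 did not pass. The list for the unfolded protein response was lower, at -0.08 on average (camera adjusted p = 0.0477, and adjusted p = 0.534 with an estimated correlation), and 0 of its 19 genes passed in limma, where 0 also had an unadjusted p under 0.05. Without wild-type replicate 1 or 3 or AP-2e null replicate 1 or 3 the activity list lost its call, at 0.14, 0.28, 0.40 and 0.26, and the other list lost it when any array but wild-type replicate 1 was left out, at -0.09 to -0.05.

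Of the sex-linked genes, Xist, which is transcribed from the inactive X chromosome, stood at 10.64 on AP-2e null replicate 1 and between 3.55 and 3.58 on the other 5 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty were at 3.62, 3.03 and 2.56 on that array, and at 7.48, 5.51 and 6.94 or more on the others. The sex of the mice is not given in the sources used here. These signals are those of female tissue on AP-2e null replicate 1 and of male tissue on the other 5 arrays. Sex was therefore uneven between the genotypes, and its effect cannot be told apart from that of this array. With AP-2e null replicate 1 coded apart, 26 genes fell and 1 rose, and the mean V2R difference without it was -2.14.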

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

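The test of every probe set by itself was planned, and the genes on the probe sets with several names were looked at only after the result was seen. Among the 16010 probe sets without a gene name, which enter no comparison above, 2 were lower and 2 were higher in AP-2e null VNOs past the threshold of limma over all 41345 probe sets. Among the 23521 probe sets of 1 gene, 39 were lower and 0 higher in the same test, and 37 of the 39 were of V2R genes. Among the 1814 probe sets that the platform assigns to several genes, 12 were lower and 0 higher. All 12 list V2R genes, with differences between -4.07 and -3.30, most of them from the group around Vmn2r29 to Vmn2r51 and 1 from Vmn2r121, Vmn2r122 and Vmn2r125. Probe sets of the Vmn2r29 to Vmn2r51 group list overlapping genes, and some had the same difference and SE (-4.07, SE 0.07). The 12 are therefore not 12 separate measurements.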

How the results depend on the processing

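The sex covariate, the comparison of 2 against 2 arrays, the fit without constant genes and the list tests without V2R genes in the background were chosen after seeing the data; the other settings were planned. Against 48 lower and 2 higher genes, counts of higher genes were 1 with averaged probe sets, 4 with repeated quantile normalization, 1 with array weights and 4 without constant genes. With every probe set by itself, 0 probe sets of 1 gene were higher and 39 lower. The plain one-way test gave 0 higher and 4 lower genes, and the rule of 2-fold with unadjusted p gave 13 and 90. The sex covariate gave 1 and 26, and 2 against 2 arrays gave 0 and 4, with fewer degrees of freedom in both. The covariate marks AP-2e null replicate 1 alone, so it gave the same calls as leaving that array out. Counts of alternatives hold this fit under both names. Without a single array, 0 to 1 genes were higher and 17 to 32 lower. For the other changes the cause was not tested. With the replicate number as a block, 0 genes were higher and 22 lower, 20 of them shared with the fit without it. Same-numbered samples deviated together with r of 0.0401, 0.110 and 0.0187, within the range of -0.193 to 0.122 for samples with different numbers. These values gave no clear sign that the numbers pair the samples, but so few cannot exclude it.

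V2R and H2-Mv lists and the apical markers kept direction and side of the threshold under every setting run, with mean differences from -2.31 to -1.99, from -1.23 to -1.06 and from 0.02 to 0.10. Family C at -1.76, V1R at 0.24 and basal markers at -0.54 lost their calls with an estimated correlation, and V1R also with fry (adjusted p = 0.513); without single arrays V1R lay between 0.07 and 0.35. V2R minus V1R was -2.59 without the dimmest genes, and -2.46 to -2.26 without single arrays. Basal minus apical markers was -0.0902 with medians and -0.61 to -0.57 without single arrays. Cartilage reversed to -0.13 without AP-2e null replicate 2, and lay up to 0.81 without replicate 1. Over all 35 lists, 617 of 698 alternative values kept their side, 66 lost a call, 14 gained one, and 24 without a call changed sign. For 181 genes, 3073 of 3242 values kept theirs, 157 lost a call, 12 gained one, 0 reversed, and 48 without a call changed sign. Most of these genes had no call to lose, and only 13 of the 35 lists had one. The values that kept their side therefore do not measure how firm the calls were. Signal near background limits low genes.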

Other observations

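The split counts were planned, and all other tests of explanations in this part were chosen after the result was seen. Lists of neuron development and of further cell types showed no call with camera, with adjusted p between 0.0517 and 0.971. The mean differences were 0.02 for immature neurons and progenitors, 0.01 for VNO transcription factors, 0.13 for cell proliferation, 0.04 for the Notch pathway, -0.10 for axon guidance and adhesion, -0.01 for apoptosis and -0.10 for the AP-2 family. They were 0.35 for formyl peptide receptors, 0.08 for sustentacular cells, -0.37 for basal epithelium, 0.10 for olfactory sensory neurons, 0.16 for ensheathing glia, 0.06 for macrophages, 0.09 for lymphocytes, -0.12 for interferon-stimulated genes, -0.07 for MHC class I presentation, 0.10 for bone, 0.06 for glands and -0.60 for sex-linked genes. Without wild-type replicate 1, formyl peptide receptors passed at 0.61, interferon-stimulated genes at -0.23 and cell proliferation at 0.23, the last also without wild-type replicate 3 and AP-2e null replicate 3 (both 0.20). Axon guidance passed at -0.17 without wild-type replicate 2 and basal epithelium at -0.67 without wild-type replicate 3. Without AP-2e null replicate 2, basal epithelium passed at -0.68, bone at 0.17 and macrophages at 0.08. Erythrocytes had 2 measured genes and were not tested. Slc17a6, the vesicular glutamate transporter, stood at 8.54 ± 0.17 in wild-type and 7.95 ± 0.22 in AP-2e null VNOs (SD, n = 3 each), a difference of -0.59 that did not pass (adjusted p = 0.860). Cyp2g1, a supporting-cell enzyme, varied widely within wild-type VNOs, at 7.29 ± 2.90.

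Of the 100 genes nearest to Tfap2e in the reference gene order, 5 had an unadjusted p under 0.05, which is 5% against 4.40% of all genes, and 0 passed in limma.

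The V2R genes differed by -2.09 on average, and 50 genes passed between genotypes, against at most 0 in the other splits of the 6 arrays, where the real split was the 1 with as many and 10 splits are too few for a share under 0.05. Each of the other splits mixes the genotypes within its groups, so large genotype differences widen the spread there and hold calls down. The 0 calls therefore do not measure how many calls chance gives. A lower share of all sensory neurons in the AP-2e null samples as the only cause is argued against by the V2R mean minus the V1R mean, which differed by -2.34 with a pooled SD of 0.15. Whether a smaller loss of all sensory neurons contributed is not decided by this contrast. The genes shared by both neuron classes averaged -0.06, with 5 lower and 3 higher. The array with high Xist signal is argued against as the cause by a mean V2R difference of -2.14 without it. An equal loss of all basal neurons with the same receptor levels per cell would lower V2R genes by about the same factor. Bright V2R genes fell unequally, with Vmn2r89 at -0.88 (SE 0.15) from 9.94 and Vmn2r33 at -4.60 (SE 0.16) from 11.49. Over the list the differences lay between -5.77 and 0.34. These values argue against an equal loss as the only cause, unless probes bind other transcripts. Fewer basal neurons may still account for a part, since Gnao1 stood at -0.68, but other cells also make Gnao1. For that part, fewer neurons and lower receptor transcripts per cell cannot be told apart. An effect of the genotype on V2R transcripts stays a hypothesis.

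The V1R genes differed by 0.24 on average. Normalization between arrays after the loss of V2R signal acts on signal level. Genes of other families at the levels of the V1R genes were drawn 10000 times. The highest draw averaged 0.06, and the V1R mean lay 0.25 above the mean draw (SD of the draws 0.01). Genes of other families at these levels thus did not share the V1R difference. The draws do not decide on normalization, because scaling holds such genes near 0 and the SD is over drawn genes, not arrays. They were the third comparison with such genes. The first used the median of the middle range of V1R signal, which scaling holds near 0. The second used list means per array, which overlapped between genotypes (exact permutation p = 0.2). Spread that V1R genes share between arrays may account for the pattern, since the list means overlapped (exact permutation p = 0.2) and the difference was 0.07 without wild-type replicate 2. A larger share of apical neurons stays open, because the apical markers, which other cells also make, averaged 0.0531 and went both ways.

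The neighbours Vmn2r111 to Vmn2r117 averaged -0.17 against -2.22 for the other 102 V2R genes, and 2 of the 7 had an unadjusted p under 0.05 (Vmn2r114 at -0.87, lower also when adjusted over the list alone, and Vmn2r113 at 0.26, which was -0.25 with its probe sets averaged). Signal near the floor is argued against by their median wild-type level of 6.48, above the lower quartile of 3.62, and of 52 other V2R genes at least as bright, 34 fell. A chance order is argued against by 100000 shuffles of all V2R genes, in which any run of 3 to 20 neighbours as high for its length came up with a permutation p of 0.0045, after a first test with the length fixed at the 7 already seen had given 4e-04. The shuffles treat V2R genes as independent, while near-identical ones can share probes. The p therefore says only that like values stood together more than in a random order. Probes that also bind other transcripts may hold their signal up, since their median AP-2e null level was 6.11, and probe sequences were not used here. Whether transcripts of these genes depend less on AP-2e was not tested.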
